A study of Mus musculus with 8 samples.

How the data were processed

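Total RNA of 4T1 cells was sequenced after depletion of ribosomal RNA and strand-specific library preparation without poly(A) selection, per the labels' protocols. The 8 libraries were grouped by the hairpin named in their titles into shCTRL (3 libraries), shMEK5 (2, titled shMEK5-2) and shERK5 (3, titled shERK5-1). STAR and the mouse genome build mm10, which corresponds to GRCm38, are named in the submitters' processing notes; the aligner version, the gene annotation, the counting program and its use of strand are not given in the sources used here.

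The deposited values are CPM, reads per 1000000 of the reads that the authors assigned to 24454 genes listed by Entrez Gene number. Each library summed to 1000000, and 100% of the values above 0 were whole multiples of 1 read within 0.01 read, so that the reads behind each value could be recovered. The totals were 52045481, 42749674 and 45677176 reads in shCTRL replicates 1, 2 and 3, 41397315 and 47537332 in shMEK5 replicates 1 and 2, and 53714288, 53235570 and 44459228 in shERK5 replicates 1, 2 and 3. A count of 0 allows up to 3 reads, or between 0.0559 and 0.0725 CPM per library; such limits cover counting error only, since reads are not independent molecules. Gene symbols and coordinates came from a RefSeq table of GRCm38.p6, matched on the Entrez number, for 24374 genes, and 7 further symbols from GENCODE; 73 genes stayed unnamed. Mitochondrially encoded genes were not used here. How reads shared between gene copies were counted is not given in the sources used here. Gapdh, which has many processed copies, was listed at 1.49 CPM in shCTRL, and 38 tested genes in 16 sets held the same reads in all 8 libraries, so that histone, MHC class I and other multi-copy genes are uncertain.

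The test planned for counts was edgeR's quasi-likelihood test; because the deposited unit is CPM, the test planned for normalized values was used. It was limma with trend on log2(CPM + 1), fitted to all 8 libraries with a mean per group and no covariate, with robust empirical Bayes moderation and Benjamini-Hochberg adjustment. Genes with a CPM of at least 1 in at least 2 libraries were tested, which kept 11623 and left out 12831. Genes were called at an adjusted p under 0.05, and log2 fold changes are on the log2(CPM + 1) scale, which understates the change of genes with low values. On the recovered reads, edgeR called 5864 genes in shMEK5 and 7726 in shERK5 against shCTRL and 4671 between the knockdowns.

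The groups, tests, 22 gene lists, cell type markers and the rule for named genes were fixed before the data were examined. The rule named Map2k5 and Mapk7, 10 EMT markers, the 6 genes up and 6 down with the largest fold changes in each knockdown, 5 up and 5 down shared by both, and 5 up and 5 down between the knockdowns. Apart from the targets and EMT markers these had to pass the test and reach a mean of 5 CPM over all 8 libraries. They also had to show no overlap of the groups compared and carry an established symbol. From the lists described, up to 4 members were named, taken from the 4 with the smallest adjusted p; Krt8 and Krt18 in shERK5, Ccnd1 in shMEK5, and Malat1, Neat1 and the genes with opposite signs given under other observations were chosen after their values were seen. The lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Of the fixed list genes, 1 MHC class I gene was not matched, and some lists share members, such as Tgfb2, Axl and Ccn1 of the YAP/TAZ list, Lif of the NF-kB list and Sqstm1 of the autophagy list.

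Replicates were compared before averaging. Every pair of libraries within a group differed by more than sampling noise, with chi-square values per degree of freedom between 7.45 and 37.42, so that none was counted as a duplicate. The first principal component, with 63.2% of the variance, separated shCTRL from the knockdowns, with shMEK5 between shCTRL and shERK5, and the second, with 25.1%, separated shMEK5 from the others.

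The limma step was tested on simulated data with 200 changed genes among 11623. For shMEK5 against shCTRL, 21 of 50 genes changed 1.25-fold were recovered, 41 of 50 at 1.5-fold, 49 of 50 at 2-fold and 50 of 50 at 4-fold, with 20 calls among unchanged genes. For shERK5 against shCTRL the numbers were 24, 44, 47 and 50 with 13 such calls, and for shERK5 against shMEK5 15, 45, 46 and 50 with 17, so that false calls ran somewhat above the nominal share. The camera step was tested on separate simulated data, in which only the genes of a single random list were changed, all raised 1.5-fold. In each comparison camera called that list and 0 of the other random lists. The simulated genes varied independently, so this cannot show how often camera calls lists of genes that vary together. Far fewer genes were changed in these simulations than were called in the data, so the rates above may not carry over.

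Alternatives planned before the data were seen were RLE size factors, library sizes without the 20 highest genes, no expression filter, DESeq2 and limma-voom on the recovered reads, non-robust moderation, the replicate number as a block, fits to the libraries of the compared groups alone, a test against a fold of 1.5, leaving out each library in turn, and, for the lists, camera with an estimated correlation and fry. TMM factors, edgeR, edgeR's expression filter, pseudocounts of 0.25 and 4, and keeping 1 gene of each set with the same reads were added afterwards. The versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.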

Results

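RNA sequencing was carried out on 8 libraries of 4T1 cells, a mouse mammary carcinoma line used as a model of metastatic breast cancer. All cells carried a lentiviral short hairpin RNA. The hairpin was non-targeting in 3 libraries (shCTRL), directed against MEK5 in 2 libraries (shMEK5) and against ERK5 in 3 libraries (shERK5). There was 1 hairpin per target. MEK5, the product of Map2k5, is the kinase that activates ERK5, the product of Mapk7. The series asks how this kinase pair bears on the epithelial-mesenchymal transition (EMT), the shift of epithelial cells towards a motile state, in breast cancer. Depth ranged from 41397315 to 53714288 gene-assigned reads per library, so 1 read was worth between 0.0186 and 0.0242 CPM, reads of a gene per 1000000 reads assigned to genes. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

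Each hairpin lowered the transcript of its own target. Map2k5 (Entrez Gene 23938; chromosome 9, 63163768 to 63381682, GRCm38) stood at 36.3 ± 0.997 CPM (SD, n = 3) in shCTRL and at 14.2 ± 0.216 CPM (SD, n = 2) in shMEK5, which is 39.2% of the control. Its log2 fold change was -1.29 (SE 0.06, limma adjusted p = 1.84e-07). In shERK5, Map2k5 was at 36.7 ± 0.475 CPM (SD, n = 3), with a log2 fold change of 0.01 (SE 0.05, adjusted p = 0.848). Mapk7 (Entrez Gene 23939; chromosome 11, 61488812 to 61494267, GRCm38) stood at 26.8 ± 1.61 CPM (SD, n = 3) in shCTRL and at 6.53 ± 0.173 CPM (SD, n = 3) in shERK5, 24.4% of the control, with a log2 fold change of -1.88 (SE 0.07, adjusted p = 4.56e-08). Mapk7 also fell in shMEK5, to 19.5 ± 1.19 CPM (SD, n = 2), by a smaller log2 fold change of -0.44 (SE 0.08, adjusted p = 0.000923). Between the knockdowns, Map2k5 was higher in shERK5 by 1.31 (SE 0.06) on the log2 scale and Mapk7 lower, at -1.45 (SE 0.08). Library by library, Map2k5 lay between 35.2 and 37.1 CPM in the shCTRL and shERK5 libraries and at 14.1 and 14.4 CPM in the shMEK5 libraries. Mapk7 lay between 6.33 and 6.66 CPM in the shERK5 libraries and at 18.7 CPM or more in the others.

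**Figure D1:**
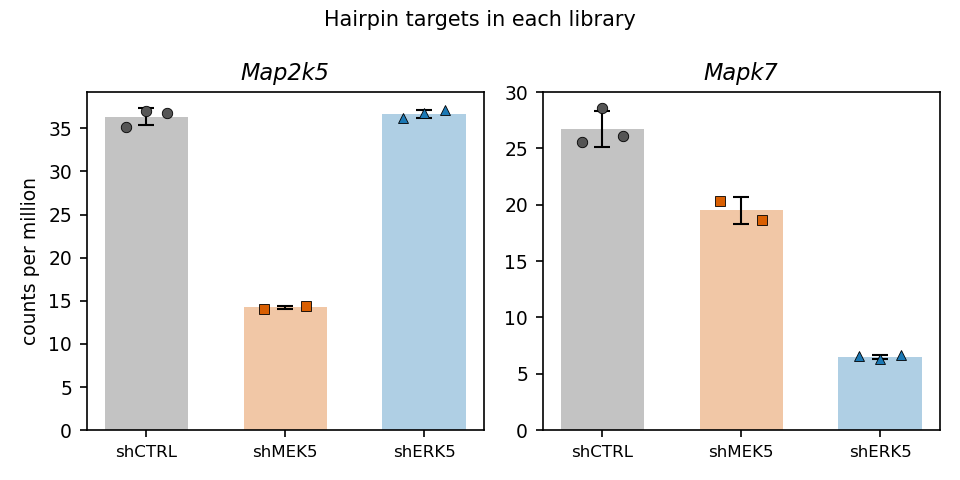
CPM of Map2k5 and Mapk7 (vertical axis) in the shCTRL (n = 3), shMEK5 (n = 2) and shERK5 (n = 3) libraries; points are libraries, bars are group means and error bars are SD. Map2k5 is at 14.1 and 14.4 CPM in the shMEK5 libraries, and Mapk7 lies between 6.33 and 6.66 CPM in the shERK5 libraries.

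Which genes follow the loss of MEK5 was asked by comparing shMEK5 with shCTRL. Interferon-induced genes rose together in shMEK5. All 35 tested members of the type I interferon list rose, with a median log2 fold change of 1.68 (quartiles 1.27 and 2.13). They included Usp18, a brake on interferon receptor signalling, which went from 0.782 ± 0.236 CPM (SD, n = 3) to 16.4 ± 0.827 CPM (SD, n = 2), Ifit1, an RNA-binding antiviral protein, at 2.26 (SE 0.07), and the guanylate-binding protein gene Gbp3 at 2.56 (SE 0.10). Vim, the mesenchymal intermediate filament vimentin, fell to 858 ± 18.6 CPM (SD, n = 2) from 1944 ± 242 CPM (SD, n = 3). Cdh1, the epithelial adhesion protein E-cadherin, rose to 55.6 ± 0.311 CPM (SD, n = 2) from 37.4 ± 0.224 CPM (SD, n = 3). By limma, 5663 of the 11623 tested genes changed, 2684 upwards and 2979 downwards, and 191 and 126 of these by at least 2-fold. Which direction held more genes depended on the scaling: with RLE size factors 2882 rose and 2783 fell.

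The genes with the greatest rise in shMEK5 under the naming rule were Usp18 (log2 fold change 3.30, SE 0.11), the antiviral gene Rsad2 (3.11, SE 0.13), the chemokine gene Cxcl10 (3.11, SE 0.14), the homeobox gene Rhox5 (2.68, SE 0.10), the stress-inducible growth arrest gene Gadd45b (2.67, SE 0.20) and Rtp4, another interferon-induced gene (2.66, SE 0.10). Their adjusted p-values ran from 4.43e-08 for Usp18 to 3.07e-05 for Gadd45b. The greatest falls were those of Fcgrt, the neonatal Fc receptor (-2.27, SE 0.10), the urea transporter gene Slc14a1 (-2.22, SE 0.08), the matrix protease gene Mmp3 (-2.07, SE 0.13), the glycosyltransferase gene Mgat3 (-2.05, SE 0.13), Sned1 (-1.84, SE 0.11) and the histone gene H3c2 (-1.82, SE 0.16). Mmp3, stromelysin-1, dropped from 244 ± 43.7 CPM (SD, n = 3) to 56.6 ± 0.312 CPM (SD, n = 2). Of 64 tested replication-dependent histone genes, 49 fell and 0 rose, with a median of -1.03. Histone genes are near-identical copies, 6 of the 64 held the same reads as another gene in all libraries, and single histone values are therefore uncertain.

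Among the EMT markers, Cdh1 rose in shMEK5 by 0.56 (SE 0.07, adjusted p = 7.25e-05) and Vim fell by 1.17 on the log2 scale (SE 0.09, adjusted p = 9.37e-06). Fn1, the matrix protein fibronectin, rose by 0.22 (SE 0.08, adjusted p = 0.0332), a call that was lost without shMEK5 replicate 1 (0.08, adjusted p = 0.389), without shCTRL replicate 1 (0.20, adjusted p = 0.0922) and without shCTRL replicate 2 (0.22, adjusted p = 0.0795). Epcam, an epithelial adhesion molecule, had a log2 fold change of 0.10 (SE 0.10, adjusted p = 0.401), and the EMT transcription factor genes Zeb2 (0.10, SE 0.11), Twist1 (0.19, SE 0.08) and Snai1 (0.26, SE 0.12) did not pass the test. Cdh2 and Snai2 had 0 reads in every library, which allows up to 0.0725 CPM in the shallowest library. Zeb1 had 1 read over the shCTRL libraries, 7 over the shMEK5 libraries and 0 over the shERK5 libraries.

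Camera called 5 of the 22 gene lists in shMEK5. The interferon list was called with adjusted p = 1.31e-26, and the call held at adjusted p = 0.00357 with an estimated correlation. Adjusted over the list alone, 35 of its 35 tested members rose. In the list of NF-kB targets, cytokines and chemokines, 19 of 22 tested members rose and 2 fell (20 and 2 adjusted over the list alone), among them the adhesion molecule gene Icam1 (1.48, SE 0.06) and Nfkbia, the NF-kB inhibitor (1.05, SE 0.06). That list had adjusted p = 3.42e-08 by camera and adjusted p = 0.178 with an estimated correlation. Of the YAP/TAZ targets, genes driven by the Hippo pathway co-activators, 13 of 16 rose and 0 fell, as they did adjusted over the list alone (camera adjusted p = 6.35e-06; adjusted p = 0.203 with an estimated correlation). Ccn2 rose by 2.01 (SE 0.07), Tgfb2 by 2.31 (SE 0.11) and Ccn1 by 1.97 (SE 0.11). In the MHC class I presentation list, 11 of 17 rose and 3 fell, also adjusted over the list alone, with the peptide transporter gene Tap1 at 0.75 (SE 0.08) and the immunoproteasome gene Psmb8 at 0.73 (SE 0.08). Its camera adjusted p was 0.00483, and adjusted p = 0.203 with an estimated correlation. Of the tested members of this list, 0 held the same reads as another gene in all libraries. How reads shared between class I heavy chain genes were counted is not given, which leaves their own values uncertain. In the autophagy and lysosome list, 16 of 30 fell and 3 rose, also adjusted over the list alone (median -0.21, camera adjusted p = 0.0101; adjusted p = 0.637 with an estimated correlation), and the falling members included the autophagy receptor gene Sqstm1 (-0.59, SE 0.04) and the cathepsin gene Ctsd (-0.47, SE 0.05).

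The remaining 17 lists were not called in shMEK5. In the epithelial list 9 of 31 rose and 6 fell (adjusted p = 0.414), with Cdh1 and the protease gene St14 (0.71, SE 0.05) among the former and the keratin genes Krt8 (-0.53, SE 0.05) and Krt18 (-0.60, SE 0.06) among the latter. In the mesenchymal and matrix list 11 of 18 rose and 4 fell (adjusted p = 0.0577), with Inhba, an activin subunit, at 1.68 (SE 0.08), Postn, periostin, at 1.30 (SE 0.10) and S100a4 at -0.97 (SE 0.07). Both counts were the same adjusted over the list alone. Postn passed the expression filter through the shMEK5 libraries alone, which favours its rise there. G2/M genes went down in 10 and up in 3 of 30 (8 and 3 adjusted over the list alone; adjusted p = 0.0526), whereas S phase genes went up in 13 and down in 5 of 30 under either adjustment (adjusted p = 0.0526), with the replication licensing gene Cdc6 at 1.08 (SE 0.08). Integrin and actin genes went up in 17 and down in 9 of 41 (18 and 10 adjusted over the list alone; adjusted p = 0.0891), with Tpm1 at 0.94 (SE 0.05).

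The comparison of shERK5 with shCTRL asked the same of ERK5. In the epithelial list 20 of 31 tested genes rose and 3 fell in shERK5 (adjusted p = 0.178 with an estimated correlation). Cdh1 reached 112 ± 8.84 CPM (SD, n = 3) in shERK5 against 37.4 ± 0.224 CPM (SD, n = 3) in shCTRL. Cldn4, the tight junction protein claudin-4, reached 288 ± 2.83 CPM (SD, n = 3) against 69.5 ± 4.26 CPM (SD, n = 3). Vim fell to 604 ± 29.8 CPM (SD, n = 3), 31.1% of its level in shCTRL. Of 30 genes of the G2/M phases, 29 fell, with a median log2 fold change of -0.82 (quartiles -1.10 and -0.61; adjusted p = 0.35 with an estimated correlation). By limma, 7360 of the 11623 tested genes changed, 3723 upwards and 3637 downwards, and 158 and 261 of these by at least 2-fold. With RLE size factors 3691 rose and 3694 fell.

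Under the naming rule, with its mean of 5 CPM over all 8 libraries, the greatest rises in shERK5 were those of Gadd45b (log2 fold change 2.83, SE 0.18), Tmem179 (2.34, SE 0.09), the related growth arrest gene Gadd45g (2.14, SE 0.17), Cldn4 (2.04, SE 0.05), the synaptic scaffold gene Dlgap1 (1.94, SE 0.11) and the transcription factor gene Arid3a (1.93, SE 0.14). Gadd45b went from 29.5 ± 7.48 CPM (SD, n = 3) to 212 ± 27.1 CPM (SD, n = 3). The greatest falls were those of Slc14a1 (-3.52, SE 0.08), Adamtsl3 (-3.19, SE 0.09), Fcgrt (-2.67, SE 0.09), the histone genes H3c2 (-2.56, SE 0.15) and H2bc9 (-2.46, SE 0.14), and Mmp3 (-2.43, SE 0.11). Slc14a1 dropped from 18.4 ± 0.456 CPM (SD, n = 3) to 0.695 ± 0.038 CPM (SD, n = 3), 3.8% of its level in shCTRL. The 12 adjusted p-values lay between 2.23e-09 for Slc14a1 and 1.37e-05 for Gadd45g. Of the 64 histone genes, 60 fell and 0 rose (median -1.53), with the same uncertainty about single copies.

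Of the EMT markers, Cdh1 rose in shERK5 by 1.56 (SE 0.06, adjusted p = 5.28e-08) and Epcam by 1.06 (SE 0.09, adjusted p = 3.45e-06), from 13.2 ± 1.44 to 28.4 ± 2.04 CPM (SD, n = 3 each). Vim fell by 1.68 (SE 0.08, adjusted p = 2.86e-07), Fn1 by 0.39 (SE 0.07, adjusted p = 0.000637) and Zeb2 by 0.36 (SE 0.10, adjusted p = 0.0104) on the log2 scale. Snai1, a repressor of Cdh1, was low, at 1.57 ± 0.244 CPM in shCTRL and 2.14 ± 0.391 CPM in shERK5 (SD, n = 3 each). Its rise of 0.29 (SE 0.11, adjusted p = 0.0421) was lost without shCTRL replicate 1 (0.21, adjusted p = 0.147), shCTRL replicate 3 (0.32, adjusted p = 0.0569), shMEK5 replicate 1 (0.29, adjusted p = 0.0504), shMEK5 replicate 2 (0.29, adjusted p = 0.0503) or shERK5 replicate 3 (0.19, adjusted p = 0.169), and with the DESeq2 test (0.44, adjusted p = 0.0821). Twist1 had a log2 fold change of 0.08 (SE 0.07, adjusted p = 0.31).

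**Figure D2:**
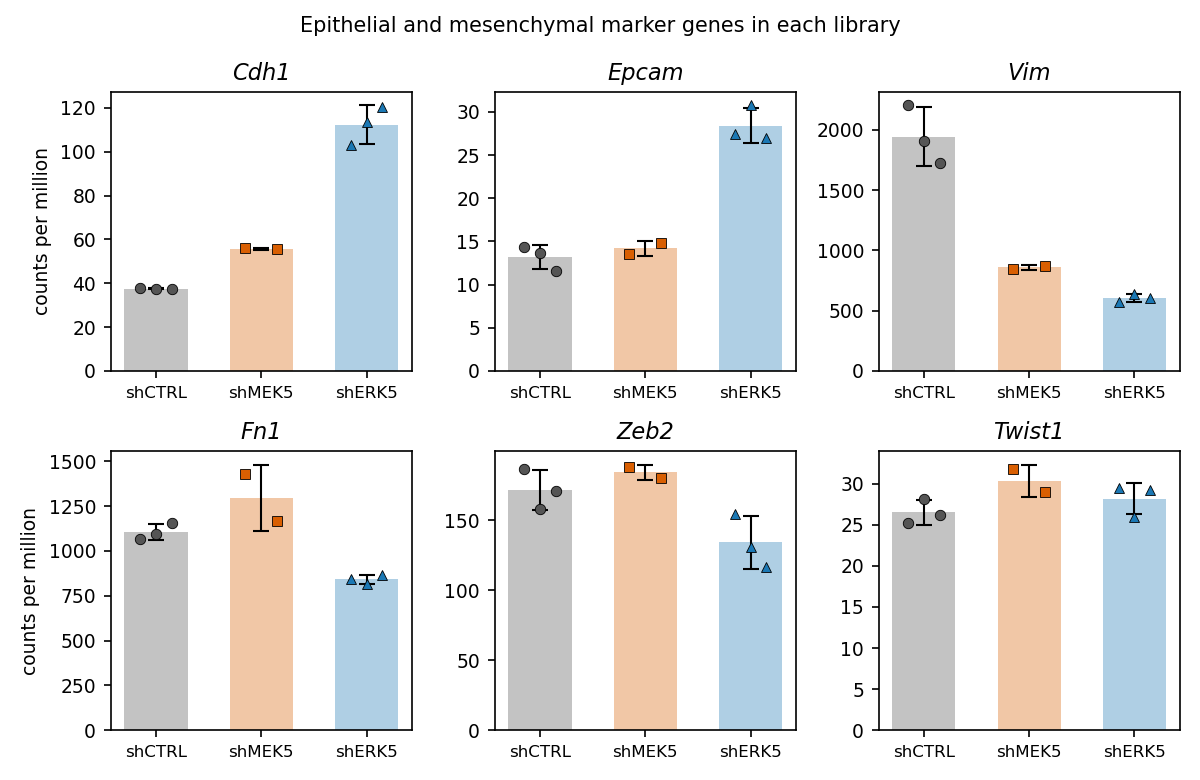
CPM of 6 EMT marker genes (vertical axes, each starting at 0) in the shCTRL (n = 3), shMEK5 (n = 2) and shERK5 (n = 3) libraries; points are libraries, bars are group means and error bars are SD. Cdh1 is at a mean of 37.4, 55.6 and 112 CPM in the 3 groups, and Vim at 1944, 858 and 604 CPM.

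Camera called 8 of the 22 lists in shERK5. With an estimated correlation it called 0 of them, while 3 lists had an unadjusted p under 0.05 and the rotation test fry called 15. In the epithelial list 20 of 31 tested members rose and 3 fell (20 and 4 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.000972; adjusted p = 0.178 with an estimated correlation). Cldn4, Cdh1, Krt19 (1.02, SE 0.05) and St14 (0.97, SE 0.05) were among those that rose, and the keratin genes Krt8 (-0.52, SE 0.05) and Krt18 (-0.52, SE 0.06) fell. G2/M genes fell in 29 of 30 under either adjustment (camera adjusted p = 4.19e-12; adjusted p = 0.35 with an estimated correlation), including the spindle genes Nusap1 (-2.41, SE 0.08) and Tpx2 (-1.16, SE 0.05) and the cyclin gene Ccnb1 (-0.86, SE 0.05). Of 30 S phase genes 16 fell and 6 rose (17 and 6 adjusted over the list alone), with the chromatin assembly gene Chaf1b at -1.11 (SE 0.07) and the helicase subunit gene Mcm7 at -0.91 (SE 0.06); camera gave adjusted p = 0.024, and it gave adjusted p = 0.625 with an estimated correlation.

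Lists of immune response genes were also called in shERK5. In the interferon list 30 of 35 rose and 0 fell under either adjustment, with a median of 0.61 (camera adjusted p = 4.48e-08; adjusted p = 0.064 with an estimated correlation), among them the oligoadenylate synthetase genes Oas1a (1.17, SE 0.07) and Oas3 (1.41, SE 0.09). In the MHC class I presentation list 12 of 17 rose and 1 fell under either adjustment, with a median of 0.73 (camera adjusted p = 0.00124; adjusted p = 0.201 with an estimated correlation). The immunoproteasome genes Psmb9 (1.49, SE 0.08) and Psmb8 (1.30, SE 0.07) and the transporter gene Tap2 (1.15, SE 0.06) were the members with the lowest adjusted p-values. Of the NF-kB and chemokine genes 17 of 22 rose and 2 fell under either adjustment (camera adjusted p = 0.000686; adjusted p = 0.35 with an estimated correlation), with Icam1 at 1.13 (SE 0.05) and the chemokine gene Cxcl16 at 1.14 (SE 0.06). Integrin and actin genes rose in 20 and fell in 8 of 41 (camera adjusted p = 0.031; adjusted p = 0.35 with an estimated correlation), with the tropomyosin gene Tpm1 at 0.80 (SE 0.04). YAP/TAZ targets rose in 8 and fell in 3 of 16 (camera adjusted p = 0.0427; adjusted p = 0.545 with an estimated correlation), and this call was lost without shERK5 replicate 1 (adjusted p = 0.0587). The counts of these last 2 lists were the same adjusted over the list alone. The mesenchymal list, with 5 of 18 up and 9 down under either adjustment, was not called (adjusted p = 0.348), nor was the autophagy and lysosome list, with 11 of 30 up and 9 down (12 and 9 adjusted over the list alone; adjusted p = 0.516).

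The lists of kinase signalling and metabolism were called in neither knockdown against shCTRL. Of the MEK5-ERK5 module and its reported targets, 5 of 17 rose and 4 fell in shMEK5, while 0 rose and 4 fell in shERK5 (adjusted p = 0.499 and 0.658). Sgk1, a kinase gene of that list, rose in shMEK5 by 0.62 (SE 0.05) and fell in shERK5 by 0.43 (SE 0.05). Ccnd1, cyclin D1, rose in shMEK5 by 0.20 (SE 0.05) and fell in shERK5 by 0.40 (SE 0.05). For the ERK1/2 output genes 4 of 21 rose and 9 fell in shMEK5, and 5 rose and 10 fell in shERK5 (adjusted p = 0.414 and 0.219), with the phosphatase gene Dusp4 at -0.66 (SE 0.06) and -0.97 (SE 0.05). MAPK cascade kinases went up in 4 and down in 7 of 22 in shMEK5 and up in 5 and down in 7 in shERK5 (adjusted p = 0.718 and 0.823). AP-1 and immediate early genes went up in 9 and down in 7 of 23, and up in 6 and down in 7 (adjusted p = 0.196 and 0.773). EMT transcription factors went up in 5 and down in 3 of 14, and up in 4 and down in 6 (adjusted p = 0.409 and 0.773), with Ets1 rising in both (0.91, SE 0.06 and 0.54, SE 0.05). Tcf3, another member of that list, fell in both (-0.49, SE 0.09 and -0.70, SE 0.08), and Sox4 fell in shERK5 (-0.71, SE 0.07). Snai3, also of that list, rose in both. Its level was 1.104 ± 0.225 CPM in shCTRL (SD, n = 3), 4.002 ± 0.706 CPM in shMEK5 (SD, n = 2) and 7.769 ± 0.631 CPM in shERK5 (SD, n = 3). TGF-beta genes went up in 11 and down in 7 of 26, and up in 8 and down in 11 (adjusted p = 0.196 and 0.823). Matrix proteases and inhibitors went up in 11 and down in 6 of 25, and up in 10 and down in 10 (adjusted p = 0.275 and 0.921), with the collagenase gene Mmp13 falling in both (-1.45, SE 0.09 and -1.54, SE 0.08). Adjusted over the list alone, the counts of these lists in shMEK5 became 6 up for the MEK5-ERK5 module, 10 up for AP-1, 4 down for the EMT transcription factors, 12 up for TGF-beta and 13 up for the matrix proteases, and the others stayed the same.

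Metabolic and stress lists had members moving in both directions and were not called against shCTRL. Glycolysis and hypoxia genes went up in 11 and down in 9 of 27 in shMEK5 and up in 14 and down in 8 in shERK5 (adjusted p = 0.499 and 0.219), with the phosphofructokinase regulator gene Pfkfb3 at 1.13 (SE 0.08) and 1.17 (SE 0.07) and Ndrg1 at -0.86 (SE 0.05) and -0.77 (SE 0.05). Nuclear oxidative phosphorylation genes went up in 9 and down in 4 of 34, and up in 17 and down in 8 (adjusted p = 0.196 and 0.219). For p53 targets 11 of 21 went up and 4 down, and 10 up and 4 down (adjusted p = 0.136 and 0.245). Cholesterol synthesis genes went up in 4 and down in 9 of 24, and up in 9 and down in 6 (adjusted p = 0.409 and 0.488). The unfolded protein and ATF4 list went up in 6 and down in 11 of 25, and up in 3 and down in 11 (adjusted p = 0.232 and 0.205). Adjusted over the list alone, 10 glycolysis genes went down in shMEK5, 8 oxidative phosphorylation genes went up and 2 down in shMEK5, 11 p53 targets went up in shERK5 and 10 unfolded protein genes went down in shERK5, and the other counts stayed the same. Median and mean differed in sign for glycolysis in shMEK5 (-0.04 and 0.04), and in shERK5 for TGF-beta (-0.07 and 0.02), the MEK5-ERK5 module (0.01 and -0.06) and the MAPK kinases (0.01 and -0.07).

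**Figure D3:**
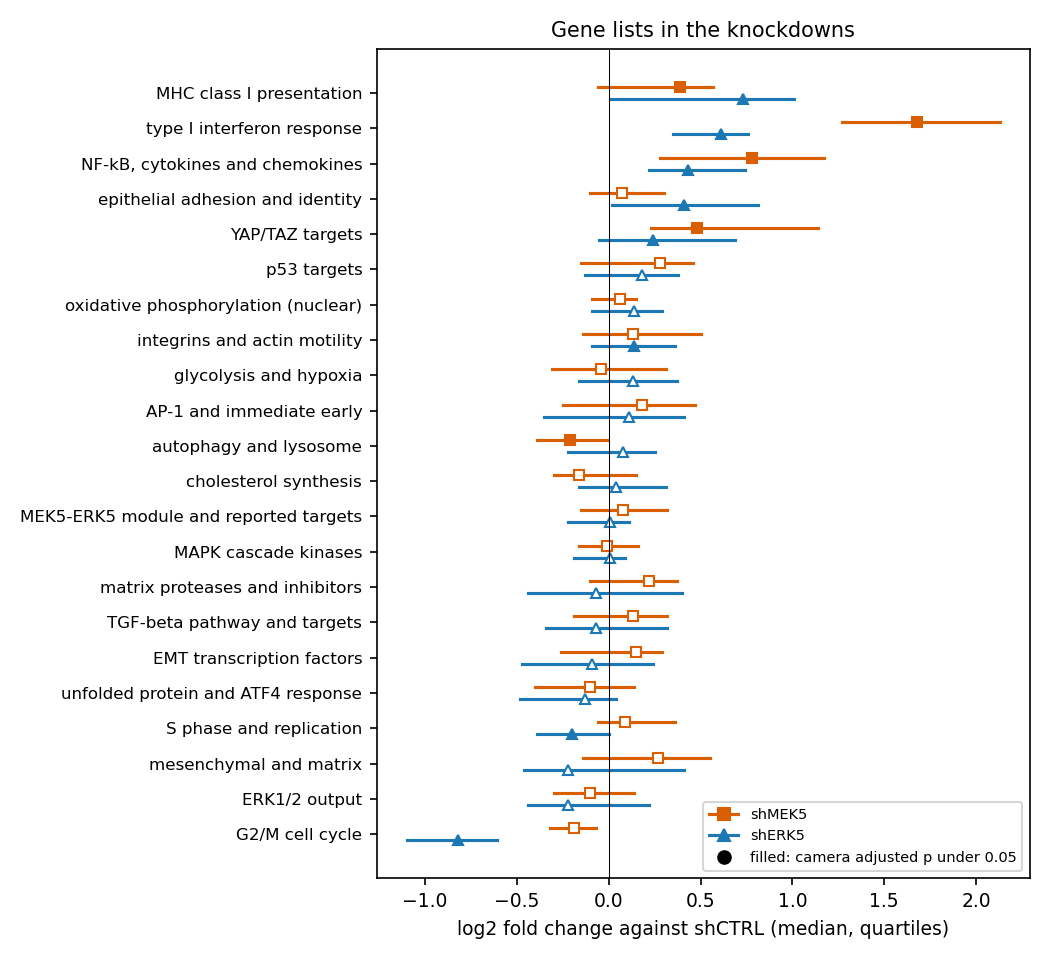
Median (marker) and quartiles (line) of the log2 fold change against shCTRL (horizontal axis) of the tested members of the 22 gene lists, in shMEK5 (squares) and shERK5 (triangles); filled markers have a camera adjusted p under 0.05. The interferon list has medians of 1.68 in shMEK5 and 0.61 in shERK5, and the G2/M list of -0.19 and -0.82.

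Whether the kinase and its substrate move the same genes was asked by setting the comparisons side by side. Under the naming rule, the growth arrest genes Gadd45b and Gadd45g, the matricellular gene Ccn1, the planar polarity gene Prickle1 and the clock gene Nr1d1 rose most in both knockdowns, and Fcgrt, Slc14a1, Mgat3, Mmp3 and Sned1 fell most in both. Prickle1 rose by 1.57 in shMEK5 (SE 0.10) and 1.57 in shERK5 (SE 0.09), and Mgat3 had log2 fold changes of -2.05 (SE 0.13) and -2.15 (SE 0.11). In all, 4064 genes changed the same way, 2028 upwards and 2036 downwards, where independent lists of the same lengths would share 859.7 and 932.2. A further 347 genes passed the test in both with opposite signs. In 50 simulations of unchanged groups set against common controls, the mean number of genes changed the same way was 0.06 and the highest 1. With no gene changed, few genes were called at all, a mean of 0.32 in shMEK5 and 0.48 in shERK5. The simulated count therefore cannot show how many of the 4064 shared calls came from the common controls.

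Across the tested genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson correlation of 0.684 and a Spearman correlation of 0.689. The simulated unchanged groups gave a mean Pearson correlation of 0.446 and Spearman correlation of 0.422 through the common controls alone. The covariance was 0.1221, against a simulated mean of 0.00409, a difference of 0.118. Both comparisons used the same 3 control libraries, too few to give each comparison 2 of its own, so part of the excess may come from the controls.

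**Figure D4:**
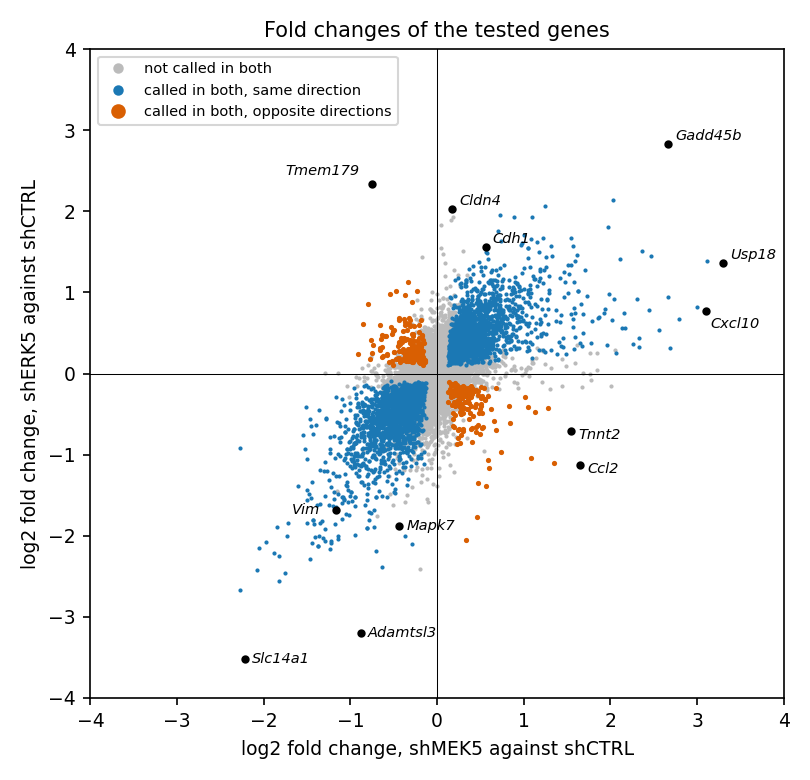
Log2 fold changes of the 11623 tested genes in shMEK5 against shCTRL (horizontal axis) and in shERK5 against shCTRL (vertical axis); blue points passed the test in both with the same sign (4064 genes), orange points with opposite signs (347 genes). Gadd45b lies at 2.67 and 2.83, Slc14a1 at -2.22 and -3.52, and Ccl2 at 1.65 and -1.13.

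Comparing shERK5 with shMEK5 tested directly where the knockdowns differed. The targets were left at unlike levels, Map2k5 at 39.2% and Mapk7 at 24.4% of the control, with 1 hairpin per target. A difference of hairpin or of depletion therefore cannot be told apart from one between the kinases. Of 35 interferon genes, 34 were lower in shERK5 than in shMEK5 (adjusted p = 0.00535 with an estimated correlation), as were 30 of 30 G2/M genes (adjusted p = 0.199 with an estimated correlation). In the epithelial list 18 of 31 genes were higher in shERK5 and 2 lower (adjusted p = 0.0721 with an estimated correlation). Cldn4 stood at 288 ± 2.83 CPM (SD, n = 3) in shERK5 and 78.4 ± 1.17 CPM (SD, n = 2) in shMEK5, and the monocyte chemokine gene Ccl2 at 2.79 ± 0.325 and 25.2 ± 3.97 CPM. By limma, 4581 of 11623 genes differed, 2561 higher and 2020 lower in shERK5, of which 47 and 143 differed by at least 2-fold. The excess of higher genes depended on the scaling, with 2281 higher and 2205 lower under RLE size factors and 2252 and 2261 with DESeq2. The count was 2864 without shMEK5 replicate 1, a fit in which the remaining shMEK5 library is assumed to vary like the other groups.

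Under the naming rule, which asks for a mean of 5 CPM over all 8 libraries, the genes most above their shMEK5 level were Tmem179 (log2 difference 3.10, SE 0.10), Cldn4 (1.86, SE 0.06), the siderophore-binding protein gene Lcn2 (1.65, SE 0.10), Rhpn2 (1.61, SE 0.10) and Lat2 (1.52, SE 0.09). Under the same rule those most below it were Ccl2 (-2.78, SE 0.14), Rhox5 (-2.37, SE 0.10), Cxcl10 (-2.34, SE 0.14), Adamtsl3 (-2.32, SE 0.10) and the cardiac troponin gene Tnnt2 (-2.26, SE 0.07). Their adjusted p-values lay between 4.09e-08 and 1.69e-06. Cdh1 was higher in shERK5 by 1.00 (SE 0.07) and Epcam by 0.95 (SE 0.10). Vim was lower, at -0.51 (SE 0.09), as was Fn1, at -0.62 (SE 0.08).

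Camera called 10 of the 22 lists between the knockdowns. Interferon genes were lower in shERK5 in 34 of 35 cases (35 adjusted over the list alone), with a median difference of -1.09 (camera adjusted p = 1.57e-22; adjusted p = 0.00535 with an estimated correlation), and G2/M genes in 30 of 30 under either adjustment, with a median of -0.62 (camera adjusted p = 4.87e-16; adjusted p = 0.199 with an estimated correlation). S phase genes were lower in 23 of 30 and higher in 0 (26 and 0 adjusted over the list alone; camera adjusted p = 2.09e-10; adjusted p = 0.199 with an estimated correlation). Epithelial genes were higher in shERK5 in 18 and lower in 2 of 31, also over the list alone, with the polarity gene Crb3 at 1.41 (SE 0.10) (camera adjusted p = 1.37e-05; adjusted p = 0.0721 with an estimated correlation). Mesenchymal and matrix genes were lower in 9 and higher in 2 of 18, and lower in 10 and higher in 2 adjusted over the list alone. For this list camera gave adjusted p = 0.000541, and adjusted p = 0.199 with an estimated correlation. Inhba was at -1.67 (SE 0.08), the tenascin gene Tnc at -1.83 (SE 0.10) and Postn at -1.49 (SE 0.10). The collagen gene Col4a1 was higher in shERK5, at 0.65 (SE 0.04). Postn passed the expression filter through the shMEK5 libraries alone, which favours its difference.

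Lysosomal and autophagy genes were higher in shERK5 than in shMEK5 in 21 and lower in 3 of 30 (camera adjusted p = 4.85e-05; adjusted p = 0.336 with an estimated correlation), including the hexosaminidase gene Hexa (0.75, SE 0.06) and Ctsd (0.57, SE 0.05). MHC class I presentation genes were higher in 10 and lower in 2 of 17 (camera adjusted p = 0.00611; adjusted p = 0.199 with an estimated correlation), with Tap2 at 0.82 (SE 0.07) and the light chain gene B2m at -0.46 (SE 0.05). YAP/TAZ targets were lower in 4 and higher in 0 of 16, with Ccn2 at -2.17 (SE 0.07) (camera adjusted p = 0.00991; adjusted p = 0.37 with an estimated correlation). The counts of these 3 lists were the same adjusted over the list alone. Cholesterol synthesis genes were higher in 13 and lower in 2 of 24 (14 and 2 adjusted over the list alone; camera adjusted p = 0.0144; adjusted p = 0.528 with an estimated correlation), with Hsd17b7 at 0.69 (SE 0.07). NF-kB and chemokine genes were lower in 9 and higher in 4 of 22 (10 and 5 adjusted over the list alone; camera adjusted p = 0.0365; adjusted p = 0.462 with an estimated correlation), and this call was lost without shMEK5 replicate 1 (adjusted p = 0.0508) or shMEK5 replicate 2 (adjusted p = 0.139).

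The other 12 lists were not called between the knockdowns. Higher and lower members in shERK5 numbered 2 and 4 of 14 for the EMT transcription factors (adjusted p = 0.156), 3 and 9 of 26 for TGF-beta genes (adjusted p = 0.0914), 4 and 5 of 17 for the MEK5-ERK5 module (adjusted p = 0.297) and 5 and 4 of 22 for MAPK kinases (adjusted p = 0.983). They numbered 4 and 4 of 23 for AP-1 genes (adjusted p = 0.46), 3 and 6 of 21 for ERK1/2 output (adjusted p = 0.172), 5 and 8 of 25 for matrix proteases (adjusted p = 0.297) and 10 and 9 of 41 for integrins and actin genes (adjusted p = 0.653). For glycolysis they were 6 and 3 of 27 (adjusted p = 0.234), for oxidative phosphorylation 8 and 3 of 34 (adjusted p = 0.714), for p53 targets 4 and 6 of 21 (adjusted p = 0.64) and for the unfolded protein response 5 and 6 of 25 (adjusted p = 0.655). Adjusted over the list alone, 7 ERK1/2 output genes, 10 matrix protease genes and 10 integrin and actin genes were lower, 6 oxidative phosphorylation and 6 unfolded protein genes were higher, and the other counts stayed the same. The MAPK kinases had a median of 0.03 and a mean of -0.02. Sgk1 was lower in shERK5 than in shMEK5, at -1.06 (SE 0.05), and Ccnd1 at -0.61 (SE 0.05).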

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

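The tests of explanations below were chosen after the results were seen, except for the other splits of the libraries, which were planned. The lists and genes in the next paragraph are among those called in the direct comparison of shERK5 with shMEK5, the lists by camera at the preset correlation of 0.01. With an estimated correlation only the interferon list was called (adjusted p = 0.00535).

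Of the gene lists, the epithelial list had a median log2 difference, shERK5 less shMEK5, of 0.32, MHC class I presentation 0.29, autophagy and lysosome 0.30 and cholesterol synthesis 0.19 (adjusted p = 0.0721, 0.199, 0.336 and 0.528 with an estimated correlation). The median was -0.46 for the mesenchymal and matrix list, -0.14 for YAP/TAZ targets, -0.62 for G2/M, -0.34 for S phase and -0.16 for NF-kB and chemokine genes (adjusted p = 0.199, 0.37, 0.199, 0.199 and 0.462 with an estimated correlation). For interferon response it was -1.09. Several named genes moved in opposite directions in the knockdowns: the difference was 3.10 for Tmem179, 1.65 for Lcn2, 1.52 for Lat2, -0.62 for Fn1, -2.78 for Ccl2 and -2.26 for Tnnt2. The rise of Fn1 in shMEK5 was lost without shMEK5 replicate 1 (0.08, adjusted p = 0.389), shCTRL replicate 1 (adjusted p = 0.0922) or shCTRL replicate 2 (adjusted p = 0.0795).

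Of 35 interferon response genes, 35 rose in shMEK5 and 30 in shERK5 (adjusted p = 0.064 with an estimated correlation), and 34 were lower in shERK5 than in shMEK5. Immune cells among the cultured cells are argued against by Lyz2, Tyrobp, C1qa and Ptprc, abundant in such cells, of which the highest value in any shMEK5 library was 0.11 CPM. These genes were picked from the fixed list of 12 macrophage and monocyte markers, of which 2 passed the expression filter. Of those 2, Cd14 rose in shMEK5, to 10.48 and 12.77 CPM in its libraries, and Cd68 fell. The scaling of the libraries is argued against as well, since with TMM factors the median of the list in shMEK5 was 1.70. A response to the hairpin or vector, unrelated to loss of the target, cannot be told apart from an effect of the knockdown, because there was 1 hairpin per target; the list differed between the hairpins by a median of -1.09. Loss of MEK5 or ERK5 stays open as the biological explanation and was not tested separately.

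Of 64 replication-dependent histone genes, 49 fell in shMEK5 and 60 in shERK5. A lower yield of RNA without a poly(A) tail is argued against as the whole source in shERK5. Small nuclear, nucleolar and related RNA genes there had a median log2 fold change of -0.13 (quartiles -0.27 and -0.03) against -1.53 for the histone genes. In shMEK5 these medians were 0.04 (quartiles -0.11 and 0.24) and -1.03. Malat1 and Neat1, left out of the former set, fell in both knockdowns, though by less than the histone medians. A shift of reads between near-identical copies is argued against too, as the whole source in either knockdown. The share of the whole family was 1.306 ± 0.182% of reads in shCTRL (SD, n = 3). It was 0.762 ± 0.008% in shMEK5 (SD, n = 2), a log2 ratio of -0.78, and 0.558 ± 0.086% in shERK5 (SD, n = 3), a log2 ratio of -1.23. Fewer dividing cells may account for part of the fall in shERK5, where 29 of 30 G2/M genes fell (median -0.82, camera adjusted p = 0.35 with an estimated correlation). The S phase genes there fell less than the histone genes, with 16 down and 6 up of 30. Their median was -0.20 (camera adjusted p = 0.625 with an estimated correlation). In shMEK5 fewer dividing cells cannot be told apart from other sources, since the cell cycle lists went different ways. The S phase genes did not fall as a set, with 13 up and 5 down of 30 and a median of 0.09 (quartiles -0.06 and 0.36). Of 30 G2/M genes 3 rose and 10 fell.

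Many genes changed the same way in both knockdowns. Chance values shared through the control libraries are argued against as the whole source, because the covariance of the fold changes was 0.1221 and the spread of the control libraries accounts for 0.00389 of it. Whole-chromosome dose differences of the control population are argued against as the main source, since the chromosome accounted for 1.74% of the variance of the mean fold change. A difference of the single control population that has nothing to do with the hairpins cannot be told apart from a shared effect, because no other control population was analysed here; 2697 of the shared genes did not pass the test between the knockdowns. A common effect of losing either kinase stays open as the biological explanation.

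For shERK5 against shCTRL, fitted to their 6 libraries alone, the real grouping gave 7201 genes, and the highest count among the other splits of the libraries was 0. The real grouping was the 1 split of 10 with as many genes, and 10 splits are too few for a share under 0.05.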

How the results depend on the processing

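The alternatives TMM, edgeR, edgeR's filter, the pseudocounts and the set of genes with the same reads were chosen after seeing the data. Counts of changed genes stayed within 1.5 times of the values reported under all alternatives but the following. Tested against a fold of 1.5, 357 genes changed in shMEK5 and 604 in shERK5, 200 differed between the knockdowns (63 higher and 137 lower in shERK5) and 166 changed the same way in both; these counts are lower by construction. Leaving out 1 library at a time, between 2864 (without shMEK5 replicate 1) and 4825 genes differed between the knockdowns, between 3929 and 6055 changed in shMEK5, between 6416 and 7278 in shERK5 and between 2903 and 4177 the same way in both. Without a shMEK5 library, the remaining one is assumed to vary like the other groups. The correlation of the fold changes was 0.626 with DESeq2 and between 0.65 and 0.696 in the other fits of all libraries. It was 0.65 with edgeR and 0.656 with limma-voom on the recovered reads. With no expression filter, a fit of 17283 genes on the log2(CPM + 1) scale, it was 0.68. The cause was not tested.

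With an estimated correlation camera called 1 list in shMEK5 and 1 between the knockdowns, interferon response in each, and 0 in shERK5 (3 at an unadjusted p under 0.05, lowest adjusted p 0.064). Fry, which does not compare a list with other genes, called 16, 15 and 16 lists in shMEK5, in shERK5 and between the knockdowns. Leaving out 1 library gave between 6 and 8 lists in shMEK5, against 5 with all libraries, and 8 in each fit without a shERK5 library; the cause was not tested. Of the 23 list calls, 23 held under the other scalings and without a filter and 21 with each library left out. Of 91 calls of the targets, EMT markers and genes with the largest changes, 83 held under RLE, TMM, DESeq2, edgeR, the block and each library left out; members named from the lists alone were not tested this way. Of the 91, the calls lost in some were those of Fn1, Cldn4, Snai1 and Rhox5 against shCTRL and Zeb2, Fcgrt, H3c2 and H2bc9 between the knockdowns, mostly with a library left out: Cldn4 in shMEK5 had adjusted p = 0.137 without shMEK5 replicate 2, Rhox5 in shERK5 0.0549 without shERK5 replicate 2, and Zeb2 0.0715, H3c2 0.0667 and H2bc9 0.0655 without shMEK5 replicate 1. No called value among these changed sign. The direction with more genes turned with the scaling: with TMM factors 2923 rose and 2763 fell in shMEK5, while without the 20 highest genes 2717 rose and 2971 fell, and of the genes changed the same way 2144 rose and 1943 fell with TMM factors.

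The replicate numbers were not taken to pair the libraries. Same-numbered shCTRL and shERK5 libraries had correlations of deviations of -0.065, -0.191 and 0.169, shCTRL and shMEK5 libraries of -0.13 and 0.031, and shMEK5 and shERK5 libraries of 0.465 and 0.518, so that pairing is left open for the last. With the replicate block, 5763 genes changed in shMEK5, 7462 in shERK5, 4435 differed between the knockdowns and 4186 changed the same way, and the correlation was 0.692. Under the block camera called 6, 7 and 10 lists; YAP/TAZ targets in shERK5 were no longer called (adjusted p = 0.052), Snai1 in shMEK5 was called (0.0426), and the other called lists and the genes of those 91 calls stayed on their side of the threshold. At a depth of 41397315 reads or more, genes under 1 CPM were left out of the tests rather than shown to be absent. Planned use of library size alone and of the CPM filter became the reported fit, and DESeq2 and the block give no CPM level for the targets, so these were not run.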

Other observations

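The ranking of genes with opposite signs, the comparison of chromosomes and the choice of Malat1 and Neat1 were made after values were seen. Markers of mammary lineages moved apart within each knockdown. Of the luminal markers, Krt8 and Krt18 fell in both, by 0.53 (SE 0.05) and 0.60 (SE 0.06) on the log2 scale in shMEK5 and by 0.52 (SE 0.05) and 0.52 (SE 0.06) in shERK5. Krt19 and the oestrogen receptor gene Esr1 rose, with log2 fold changes of 0.39 (SE 0.06) and 0.36 (SE 0.10) in shMEK5 and of 1.02 (SE 0.05) and 1.29 (SE 0.09) in shERK5. Areg, the growth factor amphiregulin, fell to a greater extent in shERK5 (-1.32, SE 0.05) than in shMEK5 (-0.58, SE 0.06), and the direct difference of -0.74 (SE 0.06) passed the limma test (adjusted p = 1.01e-05). In all, 3 of 8 tested luminal markers rose and 3 fell in shMEK5, and 3 rose and 4 fell in shERK5. Of 12 basal markers 4 passed the expression filter, Krt14 and Krt17 through the shMEK5 libraries alone. Their rise in shMEK5, from under 0.5 CPM to between 1.43 and 1.84 CPM, is therefore favoured by the filter. In shERK5 Krt14 had a log2 fold change of -0.03 (SE 0.09). Krt17 lay between 0.60 and 0.78 CPM there, against 0.11 to 0.17 CPM in shCTRL. Of the 4 tested markers 3 rose and 1 fell in shMEK5, and 2 rose and 1 fell in shERK5. These counts say little about the basal lineage.

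No lymphocyte, adipocyte or erythroid marker passed the expression filter, with highest values of 0.04, 0.14 and 0.07 CPM. Of the fibroblast markers, Postn, which passed the filter through the shMEK5 libraries alone, rose in shMEK5. Pdgfra, at between 22.5 and 46.3 CPM in the libraries, fell in shERK5 (-0.48, SE 0.14). Of the macrophage markers, Cd14, at up to 14.2 CPM, rose in both (0.59, SE 0.11 and 0.68, SE 0.10) and Cd68 fell in shMEK5 (-0.43, SE 0.10), and of the endothelial markers Egfl7, at between 39.6 and 67.1 CPM, rose in both (0.29, SE 0.05 and 0.68, SE 0.05).

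Among the 347 genes with opposite signs, those with the largest smaller change were Ccl2 (1.65, SE 0.14 in shMEK5 and -1.13, SE 0.12 in shERK5), Il18rap (1.08, SE 0.13 and -1.05, SE 0.11), Lcn2 (-0.79, SE 0.10 and 0.85, SE 0.09), Tmem179 (-0.76, SE 0.10 and 2.34, SE 0.09) and Tnnt2 (1.55, SE 0.07 and -0.71, SE 0.06). The aryl hydrocarbon receptor gene Ahr rose by 0.84 (SE 0.09) in shMEK5 and fell by 0.61 (SE 0.08) in shERK5.

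By chromosome, the 322 tested genes of the X chromosome had a median log2 fold change of -0.127 in shMEK5 and -0.179 in shERK5, below all of 10000 random gene sets of that size in each case. Chromosome 13, which carries a large histone cluster, had a median of -0.108 in each. Chromosomes 8 and 19 had medians of 0.114 and 0.118 for shERK5 against shMEK5, at or above all of 10000 such sets. Other chromosomes also lay beyond all such sets, among them 10 and 15 upwards in shMEK5, 2 downwards in shERK5, and 4 upwards and 2 downwards for shERK5 against shMEK5, so that these chromosomes do not stand alone. The ribosome-depleted libraries also held Malat1 and Neat1, long nuclear RNAs, which fell in both knockdowns: Malat1 by 0.62 (SE 0.11) and 0.49 (SE 0.09), and Neat1 by 0.49 (SE 0.07) and 0.62 (SE 0.06) on the log2 scale.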
